A study of Mus musculus with 8 samples.

How the data were processed

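RNA was collected from the thoracic aortic endothelium of 8 female mice that carried the tamoxifen-inducible endothelial recombinase Cdh5-CreERT2 and floxed Mef2c alleles, 4 injected with tamoxifen and 4 littermates injected with vehicle. Per the labels, TRIzol was flushed through the lumen of each aorta, 5 ng of total RNA was converted to biotinylated cDNA with the WT Pico protocol, and each sample, from a single aorta, was measured on an Affymetrix Mouse Transcriptome Array 1.0. The deposited values are log2 expression per transcript cluster, made by the authors with SST-RMA in Expression Console, per the labels. SST-RMA transforms the signal space and then applies background correction, quantile normalization and probe summary, so differences in overall signal between arrays were largely removed before deposit. The version of Expression Console is not given in the sources used here. All 8 columns of the table belong to the 8 samples, and each was assigned to its group by the sample titles. The labels give no array batch or date.

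The table held 72688 probe sets, of which 6732 were control probe sets of the array. The platform annotation gave 1 gene symbol to 30604 probe sets and several to 2146, and it did not list 33206 others, which are unnamed here. Repeats of one symbol within a probe set were counted as 1 symbol. Symbols were updated through the gene identifier or synonyms of the RefSeq table of assembly GRCm38.p6, which changed 1135 and matched 30602 of the 30604 probe sets with 1 symbol. These 2 steps had not been spelled out in the plan of the analysis. No genome build is named for the array values, so no coordinates are given. For the 429 symbols with more than 1 probe set, the one with the highest mean over the 8 arrays was used.

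Genes whose mean over all arrays lay above 6.14, the median of all probe sets, were tested, which left 16232 genes, 11219 of them protein-coding. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Differences are tamoxifen-treated minus vehicle-treated, on the log2 scale. Single values per array, such as the mean of a gene list, were compared with a two-sided exact permutation test over the 70 assignments of the arrays, whose smallest p is 0.0286. The number of arrays limits the precision of every value.

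The comparison, its tests, 35 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered MEF2 proteins and their reported targets, endothelial programmes, responses that tamoxifen or dissection could evoke, and markers of the other cell types of the aorta and its surroundings. They held 412 symbols, of which 365 had a probe set with 1 symbol and 306 were tested. Lists with at least 4 tested genes, 31 in all, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The result of 1 list is not reported here. Members of each list were also adjusted over the list alone. The genes named are Mef2c, the 10 genes with the smallest p in each direction whose symbols are not predicted or clone names, whether or not they passed the threshold, and up to 4 members of each list with the smallest p. Any other gene named is said to have been chosen after its values were seen. The class called predicted and clone symbols also took in symbols of olfactory and vomeronasal receptors, microRNAs and small nucleolar RNAs. It held 4831 of the 16232 genes tested.

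The test was tested on simulated data with the spread of these arrays, in which 200 of the 16232 genes were changed. It called 82% of the genes changed by 1 on the log2 scale and 93% of those changed by 2, and 7.89% of its calls were unchanged genes. Camera called a list shifted by 0.5 and 0 of the unshifted lists. The simulated genes varied independently of each other, unlike genes of one cell type, so this says little about the error rate of camera on real lists. The shares of single genes called likewise hold for 200 independent changed genes. With fewer changed genes, or with variation shared between genes, they need not hold. A lack of calls would therefore not show that no gene changed.

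Alternatives covered the filter on level, the choice of probe set, quantile normalization, centring on the array median and the variance model. Also covered were array weights, Welch's test on the same values, the thresholds, the replicate number as a block and the set test. Each array was also left out in turn. The planned covariates were smooth muscle markers and the array median, the latter taken over all probe sets. After seeing the data 3 alternatives were added: a covariate for adipocyte markers, a covariate for the signal contrast of the array (the median of its control probe sets marked pos minus that of those marked neg), and protein-coding genes only. The estimated correlation and fry were also run, as a later addition, with each array left out and under the other settings. Lists of salivary gland, kallikrein 1 family, erythroid and immunity-related GTPase genes were also made after seeing the data.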

Results

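The expression of 16232 genes was compared in thoracic aortic endothelium from 4 mice with induced endothelial deletion of Mef2c (EKO) and 4 control mice. All were female Cdh5-CreERT2-positive mice with floxed Mef2c, a gene for a MADS-box transcription factor. At 10 weeks of age they received 5 daily injections of tamoxifen (EKO) or of the vehicle, sunflower seed oil with 10% ethanol (control), and aortas were taken 14 days after the first injection. Each array held RNA flushed from a single aorta. The comparison asks which endothelial transcripts differ after deletion of Mef2c. Tamoxifen itself was given to the EKO mice alone, so the deletion and the drug differ together between the groups. Array medians over the tested genes lay between 8.43 and 8.53, and the arrays correlated pairwise with r between 0.981 and 0.993 across genes, which are not independent replicates. No arrays were identical.

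Mef2c differed between the groups by less than the spread between arrays. Its log2 expression was 9.77 ± 0.11 in control and 9.75 ± 0.20 in EKO aortas (SD, n = 4 each), a difference of -0.03 (SE 0.11, 95% confidence interval -0.28 to 0.23, limma adjusted p = 0.946). Control arrays 1 to 4 read 9.62, 9.79, 9.88 and 9.80, and EKO arrays 1 to 4 read 9.56, 9.73, 9.66 and 10.03. The sign of this difference turned under some scalings, including quantile normalization (0.02). The array has a single probe set for Mef2c that summarises the whole transcript cluster, and the labels do not say which exons were floxed. The value therefore cannot check the deletion. The other tested MEF2 genes, Mef2d (-0.10) and Mef2a (0.05), did not pass either, and the 3 genes together differed by -0.03 (exact permutation p = 0.657) and by 0.01 without EKO array 2.

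Endothelial identity genes, taken as a list, differed by less than the spread between arrays. The 19 tested endothelial identity genes averaged 12.7 in each group, with a mean difference of 0.01 (10 higher, 9 lower, camera adjusted p = 0.749). Among them Sox18 differed by 0.18, Robo4 by 0.17, Tek by -0.11 and Mmrn2 by 0.10, none past the threshold. The list mean was -0.02 without EKO array 4 and 0.05 without control array 1. The 10 reported MEF2 targets differed by a mean of -0.08 (5 higher, 5 lower, camera adjusted p = 0.854), which became 0.05 without EKO array 2, the lowest for this list, -0.14 without control array 2 and 0.07 with the array median as a covariate. The lowest was Hdac9, a class IIa histone deacetylase that binds MEF2 proteins, at -0.58 (SE 0.28, limma adjusted p = 0.584). Hdac9 read 8.31 on control array 2 and 6.94 to 7.51 on the other control arrays.

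In no gene did the difference pass the threshold. With limma 0 genes passed, the smallest adjusted p being 0.478, and 0 passed as well when each gene's variance was taken by itself, without moderation. At an unadjusted p under 0.05 limma gave 1449 genes, 880 higher and 569 lower, and the unmoderated test 1219, where about 812 are given by chance. Of limma's 1449, predicted and clone symbols made up 634 of the higher and 87 of the lower genes, and other symbols 246 and 482. Predicted and clone symbols were 4831 of the 16232 genes tested. The groups did not overlap for 987 genes, 6.08% of those tested, where chance gives 2.86% on average. This count was not made for other splits of the arrays, so it does not exclude chance. Of the 1449 genes, 82 differed by at least 1.5-fold, 50 of them higher and 32 lower.

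Of the 10 genes lowest in EKO aortas by p, none passed the threshold. Lox, the lysyl oxidase that crosslinks collagen and elastin, was 11.1 ± 0.15 in control and 10.5 ± 0.22 in EKO aortas (SD, n = 4), a difference of -0.55 (SE 0.12). Vegfd, a ligand of vascular endothelial growth factor receptors, differed by -0.53 (SE 0.12), and the B cell chemokine Cxcl13 by -1.03 (SE 0.22). Klk1b22, a glandular kallikrein, had the largest difference of the 10, at 11.96 ± 1.00 against 8.50 ± 1.16, or -3.46 (SE 0.65), a 10.99-fold lower level. Members of the kallikrein 1 family are near-identical in sequence, so its probes may be shared with theirs. Pof1b had the smallest p of all genes (-0.49, SE 0.07, unadjusted p = 8.55e-05). It averaged 7.37 in control and 6.87 in EKO arrays, and Inha 7.44 and 6.98. Control probe sets marked neg had medians of 7.34 to 7.45 on the arrays, so both genes read near or below that level. The others were Rab2b (-0.51), Inha (-0.46), Yju2 (-0.42), the Xist antisense transcript Tsix (-0.38) and Usp45 (-0.37). In all 10 the groups did not overlap, and the limma adjusted p was 0.478.

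**Figure D1:**
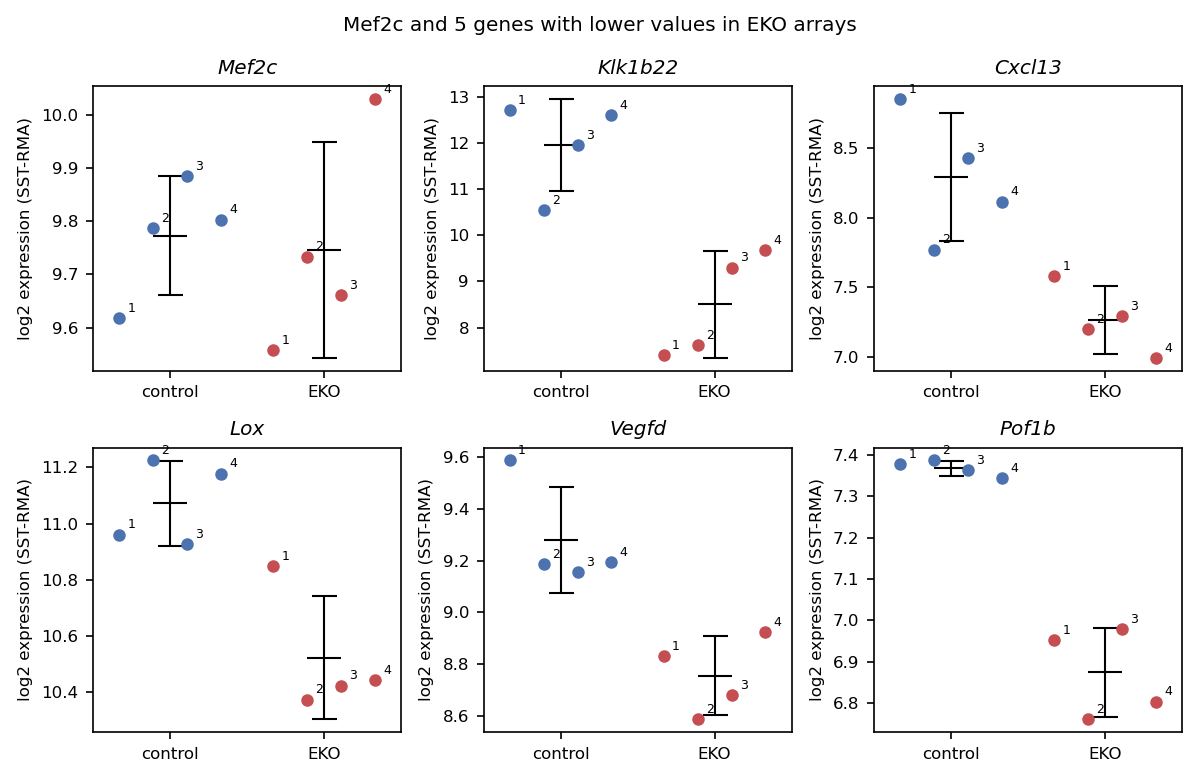
Log2 expression (SST-RMA) on each array, numbered by replicate, for Mef2c and 5 of the 10 genes with the smallest p among those lower in EKO aortas; bars are the mean ± SD of 4 arrays. Mef2c overlaps between the groups, while Klk1b22 averages 11.96 in control and 8.50 in EKO arrays, with no overlap and a limma adjusted p of 0.478.

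Of the 10 genes highest in EKO aortas by p, 7 were pseudogenes. These were Rps16-ps3 (0.52), Rpl31-ps23 (0.49), Rpl7-ps9 (0.46), Rps12-ps7 (0.42), Rps10-ps4 (0.41) and Rpl31-ps18 (0.40), all derived from ribosomal protein genes, and the major urinary protein pseudogene Mup-ps18 (0.32). The others were Btbd35f12 (0.64), the T cell receptor segment Trav13n-2 (0.43) and Ghrl (0.39), which encodes ghrelin. Ghrl averaged 5.99 in control and 6.38 in EKO arrays. Its control mean lay below the level filter of 6.14, which it passed only on the mean over both groups. The groups did not overlap in these 10 either, their SEs lay between 0.07 and 0.12, and each had an adjusted p of 0.478. Pseudogene probes can also read the parent transcript, so these values are uncertain. In control and EKO arrays Rps10-ps4 averaged 6.14 and 6.55, Mup-ps18 6.66 and 6.98, Rps16-ps3 6.77 and 7.29, and Trav13n-2 6.92 and 7.35. Such means lie near or below the medians of the control probe sets marked neg (7.34 to 7.45). The other ribosomal pseudogenes named here lay above them.

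Interferon-response genes were the only list called by camera at the preset correlation. Of 12 tested genes 11 were higher in EKO aortas, with a mean difference of 0.30 (8.23 ± 0.14 against 8.54 ± 0.43, SD, n = 4) and a camera adjusted p of 0.00395. With an estimated correlation the adjusted p was 0.981, with fry 0.895, and the exact permutation p of the list mean was 0.286. The antiviral genes Ifit3 (0.67), Ifit1 (0.60), the deubiquitinase Usp18 (0.41) and the ubiquitin-like Isg15 (0.19) had the smallest p, and 0 members passed over all genes or adjusted over the list alone. EKO array 2 was highest. Without it the mean difference was 0.10 and the camera adjusted p 0.0819. The call was also lost with the level filter at the 75th percentile (0.33, adjusted p 0.286) and with the array median (0.13, 0.408) or the signal contrast (0.19, 0.296) as a covariate.

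The 11 leukocyte adhesion and NF-kB genes were each higher in EKO aortas, by a mean of 0.30, which missed the threshold (camera adjusted p = 0.0707, exact permutation p = 0.371; adjusted p = 0.981 with an estimated correlation). Ccl5 differed by 0.50, Il1b by 0.41, Tnfaip3 by 0.37 and Csf1 by 0.24. EKO array 2 was again highest, and without it the mean was 0.11. The list passed the threshold when control array 3 (0.39) or EKO array 1 (0.37), 3 (0.37) or 4 (0.33) was left out. None of these calls held with an estimated correlation in the same fits (adjusted p = 0.825 to 0.988) or with fry (0.648 to 0.992). It also passed with quantile normalization, with the replicate number as a block and with protein-coding genes alone (0.30 in each), and with an estimated correlation the adjusted p was then 0.959, 0.999 and 0.742. Markers of neutrophils were highest on EKO array 2 too. The 5 tested averaged 6.91 ± 0.80 in control and 7.61 ± 1.18 in EKO aortas, with S100a8 at 1.15, S100a9 at 1.13, Ngp at 0.64 and Ltf at 0.13 (list mean 0.70, camera adjusted p = 0.352), and without EKO array 2 the mean was 0.13. With protein-coding genes alone the neutrophil list passed (0.0290), but not with an estimated correlation (adjusted p = 0.955).

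Lists of vessel wall and signalling genes did not pass. Elastic fibre genes differed by a mean of -0.16 (9 of 11 lower, camera adjusted p = 0.392), and passed at -0.27 without EKO array 1, and at -0.27 with smooth muscle markers as a covariate. With an estimated correlation the adjusted p was 0.825 and 0.916 in these fits and 0.981 over all 8 arrays without a covariate, and with fry 0.230, 0.187 and 0.895. The mean was -0.09 without control array 4 and 0.03 with the array median as a covariate. Fibroblast markers were lower as well (-0.29) and passed in the same covariate fit, and EKO array 1 was the highest EKO array for both lists (11.35 and 9.10). Lox was their single member past the threshold adjusted over the list alone (limma adjusted p = 0.0202), beside Loxl1 (-0.29), Fbln1 (-0.27) and Ltbp4 (-0.11). Basement membrane genes differed by -0.11 (7 of 11 lower, 0.410), with Lama4 at -0.44, Nid1 at -0.37, Lamb2 at -0.26 and Hspg2 at -0.22. Growth factors acting on smooth muscle differed by -0.10 (8 of 13 lower, 0.749), by 0.03 without control array 2 and by -0.18 without control array 3. Tgfb3 was lowest, at -0.67 (SE 0.17, limma adjusted p = 0.0560 over the list alone), followed by Igf1 (-0.23), Pdgfd (-0.22) and Pdgfc (-0.16). Metalloproteinases and their inhibitors differed by -0.10 (8 of 10 lower, 0.392), with Mmp19 at -0.18, Timp4 at -0.16, and Adamts9 and Timp2 at -0.11. Flow-responsive genes differed by -0.14 (9 of 12 lower, 0.422), with Thbd at -0.31, Nos3 at -0.28, Nqo1 at -0.26 and the connexin Gja4 at -0.13. Single arrays moved the basement membrane mean to -0.17 (without EKO array 1), the metalloproteinase mean to -0.07 (without control array 4) and the flow-responsive mean to -0.08 (without EKO array 2).

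Of the other endothelial lists, those of arterial and Notch, junction, and TGF-beta and BMP genes lay close to 0. Arterial and Notch genes differed by a mean of -0.01 and a median of 0.01 (camera adjusted p = 0.937), with Cxcr4 at 0.52, Hey1 at -0.35, Bmx at -0.13 and Acvrl1 at 0.07. Junction genes had a mean of -0.01 and a median of 0.03 (0.879), with Jup at -0.31, Ocln at 0.22, Esam at 0.11 and Cdh5, the VE-cadherin gene, at 0.08. Genes of TGF-beta and BMP responses had a mean of -0.01 and a median of 0.01 (0.937), with Skil at -0.15, Id1 at 0.15 and Bmp6 at -0.16. These 3 means turned sign when single arrays were left out, reaching 0.04 for the arterial list (without control array 1), 0.04 for junctions (without EKO array 1) and 0.07 for TGF-beta and BMP responses (without EKO array 4), against -0.04, -0.07 and -0.08 at the lowest. Genes of endothelial-to-mesenchymal transition had a mean of 0.12 (0.852), with Acta2 at 0.74, Tagln at 0.61, Fn1 at -0.23 and Vim at 0.05. Without EKO array 1, where Tagln read 11.03, the mean of this list was 0.01, and without control array 2 it was 0.23. Among the MEF2 targets Hrc stood at -0.10, Klf15 at 0.08 and Egr2 at -0.07.

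Metabolic and stress lists did not pass either without a covariate and over all genes tested. Fatty acid handling genes differed by a mean of -0.23 (9 of 12 lower, camera adjusted p = 0.854), with Pparg at -0.56, Acadm at -0.50, Fabp4 at -0.45 and Gpihbp1 at 0.16. Their mean was 0.05 without EKO array 2 and -0.51 without EKO array 1. With the array median as a covariate it turned to 0.51 and passed (camera adjusted p = 0.00646, 0.927 with an estimated correlation, 0.826 with fry), and with the signal contrast it was 0.23. Cholesterol synthesis genes differed by -0.09 (12 of 15 lower, 0.392), with Mvk at -0.20, Srebf2 at -0.15 and Ebp at -0.09 against Mvd at 0.09. Oestrogen-responsive genes, of interest because tamoxifen binds the oestrogen receptor, differed by -0.05 (0.854), with Pgr at -0.40 and Myc at 0.32. Aryl hydrocarbon and xenobiotic genes differed by -0.18 (4 of 5 lower, 0.392), with Tiparp at -0.37, Cyp1b1 at -0.20 and Gsta4 at -0.13. Immediate early and heat shock genes differed by 0.17 (7 of 11 higher, 0.352), with Fosb at 0.86, Dusp1 at 0.56, Zfp36 at 0.29 and Atf3 at 0.19. Fosb read 7.61, 9.31, 6.67 and 6.01 on EKO arrays 1 to 4, against a control mean of 6.54. Circadian genes had a mean of -0.07 and a median of 0.00234 (0.983), with Arntl at -0.76, Npas2 at -0.33, Dbp at 0.29 and Clock at -0.23. Arntl read 9.51 on EKO array 1 and 7.24 to 7.99 on the other EKO arrays. Cell cycle genes had a mean of -0.02 (0.983), with Ube2c at -0.23, Ccna2 at -0.11, Mcm2 at -0.10 and Mcm3 at 0.10. Genes of p53 and senescence had a mean of -0.02 (0.913), with Sesn2 at -0.14, Trp53inp1 at 0.12, Phlda3 at 0.07 and Mdm2 at -0.06. The cell cycle mean was 0.11 without EKO array 3 and -0.17 without EKO array 2. That of p53 and senescence was 0.04 without control array 4, -0.09 without control array 1 and 0.14 with the array median as a covariate, with which cholesterol synthesis stood at 0.07. Immediate early genes passed with protein-coding genes alone (0.0188), but not with an estimated correlation (adjusted p = 0.742). Other means shrank or grew with single arrays left out, to -0.04 and -0.15 for cholesterol synthesis (control arrays 3 and 1), -0.01 and -0.10 for oestrogen response (EKO arrays 4 and 3), -0.27 for xenobiotic genes (EKO array 4), 0.08 for immediate early genes and -0.04 for circadian genes (both control array 2).

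**Figure D2:**
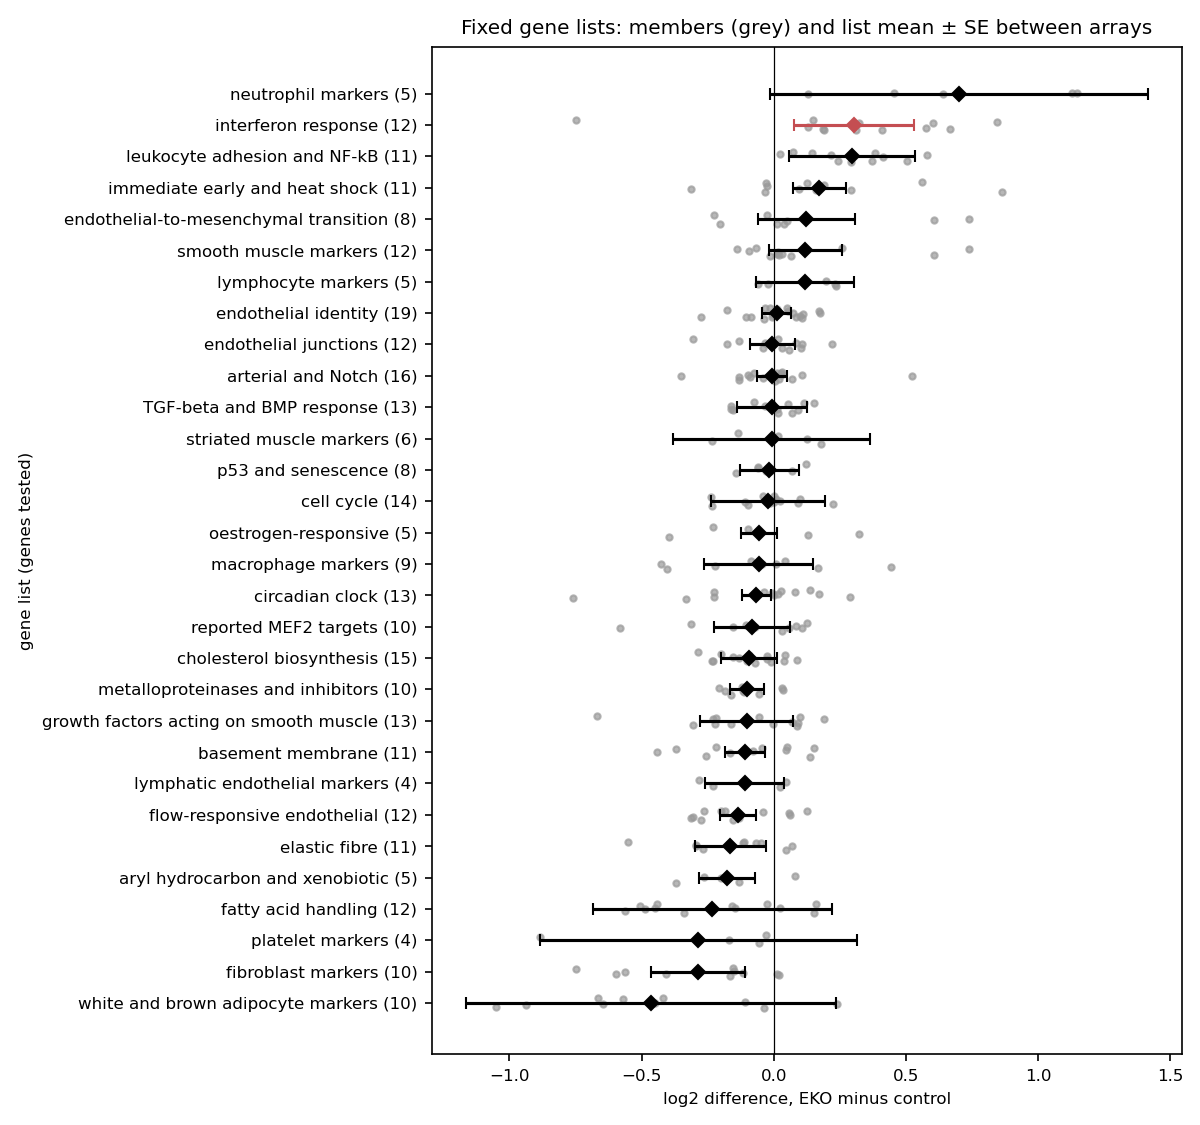
Log2 differences, EKO minus control, for 30 of the 31 gene lists tested, with members in grey and the list mean as a diamond; bars are the SE of that mean from the spread between 4 arrays per group. The interferon response list, in red, is the single list with a camera adjusted p under 0.05 (0.00395 at the preset correlation, 0.981 with an estimated one).

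Adipocyte markers varied more between arrays of a group than between the groups. White and brown adipocyte markers averaged 9.15 ± 1.05 in control and 8.69 ± 0.92 in EKO arrays (mean difference -0.46, 9 of 10 lower, camera adjusted p = 0.392, exact permutation p = 0.514), with Cox8b at -1.05, Adipoq at -0.67, Ppargc1a at -0.45 and Retn at -0.42. With the array median as a covariate the difference turned to 0.69 and passed (camera adjusted p = 0.00176). The adjusted p was 0.927 with an estimated correlation and 0.826 with fry. With the signal contrast as a covariate the difference was 0.32. The array median over all probe sets was highest on EKO array 2 (6.24), where the adipocyte mean was lowest (7.58). It was lowest on control array 4 (6.06), with an adipocyte mean of 9.91. The covariate may thus carry adipocyte content itself, so the turned sign cannot be read as a group difference. Ucp1, the brown fat uncoupling protein, chosen after its values were seen, ranged from 11.1 to 16.7 over the 8 arrays. The adipocyte list mean followed the first principal component, which held 35.2% of the variance (Pearson r = 0.979, permutation p = 7.0e-05, adjusted over 3 relations 0.000210; Spearman rho = 0.952, permutation p = 0.00114, adjusted 0.00342). Pearson r was 0.968 without the 2 arrays farthest from the median, and 0.984 and 0.983 within control and EKO arrays. The component was computed from the tested genes, adipocyte markers among them, so part of this correlation is built in.

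Fibroblast markers differed by a mean of -0.29 (8 of 10 lower, camera adjusted p = 0.140). Among them Dcn was at -0.60, and Col1a2 and Col3a1 at -0.15. Pi16 was at -0.75, and read 8.68 on EKO array 2 and 9.77 to 10.03 on the other EKO arrays. Without control array 2 the fibroblast list passed the threshold at -0.37, as did the adipocyte list at -0.87. For both the adjusted p in that fit was 0.884 with an estimated correlation and 0.756 with fry. The adipocyte difference was -0.10 without EKO array 2 and -0.13 without control array 3. The fibroblast list also passed without a level filter (-0.29), with quantile normalization (-0.30) and with smooth muscle markers as a covariate (-0.38), where the adjusted p with an estimated correlation was 0.752, 0.959 and 0.916. Over all 8 arrays that p was 0.981, with fry 0.895, and with the array median as a covariate the mean was 0.0031. Smooth muscle markers differed by 0.12 (camera adjusted p = 0.749), with Myocd at 0.26 and Cnn1 at -0.14 beside the Acta2 and Tagln values above, by 0.01 without EKO array 1 and by 0.19 without EKO array 4. Macrophage markers differed by -0.06 (0.854), with Csf1r at 0.44, Itgam at -0.43, Adgre1 at -0.40 and Cd68 at 0.17, by 0.01 without control array 3, by -0.23 without control array 2, and by 0.23 with the array median as a covariate. Lymphocyte markers differed by 0.12 (0.749), with Cd3g at 0.24, Cd3e at 0.23, Cd3d at 0.20 and Cd79a at -0.06, by -0.04 without EKO array 2, the highest for this list, and by 0.20 without control array 4. Platelet markers differed by -0.28 (0.854), with Ppbp at -0.88, Pf4 at -0.17, Itga2b at -0.06 and Gp9 at -0.03. Their mean was 0.06 without EKO array 1 and -0.63 without control array 2. Striated muscle markers had a mean of -0.01 and a median of 0.01 (0.854), with Tnnt3 at -0.23, Tnnt2 at 0.18, Myl1 at -0.13 and Ckm at 0.12, a mean of 0.31 without control array 4, -0.19 without EKO array 1, and 0.50 with the array median as a covariate. Lymphatic markers differed by -0.11 (0.854), with Pdpn at -0.28, Lyve1 at -0.23, Mmrn1 at 0.05 and Flt4 at 0.02, by -0.02 without control array 4 and by -0.23 without control array 2.

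Among lists with fewer than 4 tested genes, the erythrocyte markers Slc4a1, the band 3 anion exchanger, and Alas2, the erythroid enzyme that starts haem synthesis, differed by -0.85 and -1.02. Both passed adjusted over the list alone (limma adjusted p = 0.0195) and neither over all genes (0.524 and 0.528); their mean had an exact permutation p of 0.0571. The Schwann cell marker S100b differed by -0.55 (limma adjusted p = 0.0562 over the list alone), and by -0.31 without EKO array 2. The mesothelial markers Upk3b (-1.09) and Lrrn4 (-0.87) had an exact permutation p of 0.400, and their mean difference went from -0.98 to -0.18 without control array 4. In the planned lists reported here other than the erythrocyte and elastic fibre ones, 0 members passed by limma, over all genes or adjusted over the list alone.

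**Figure D3:**
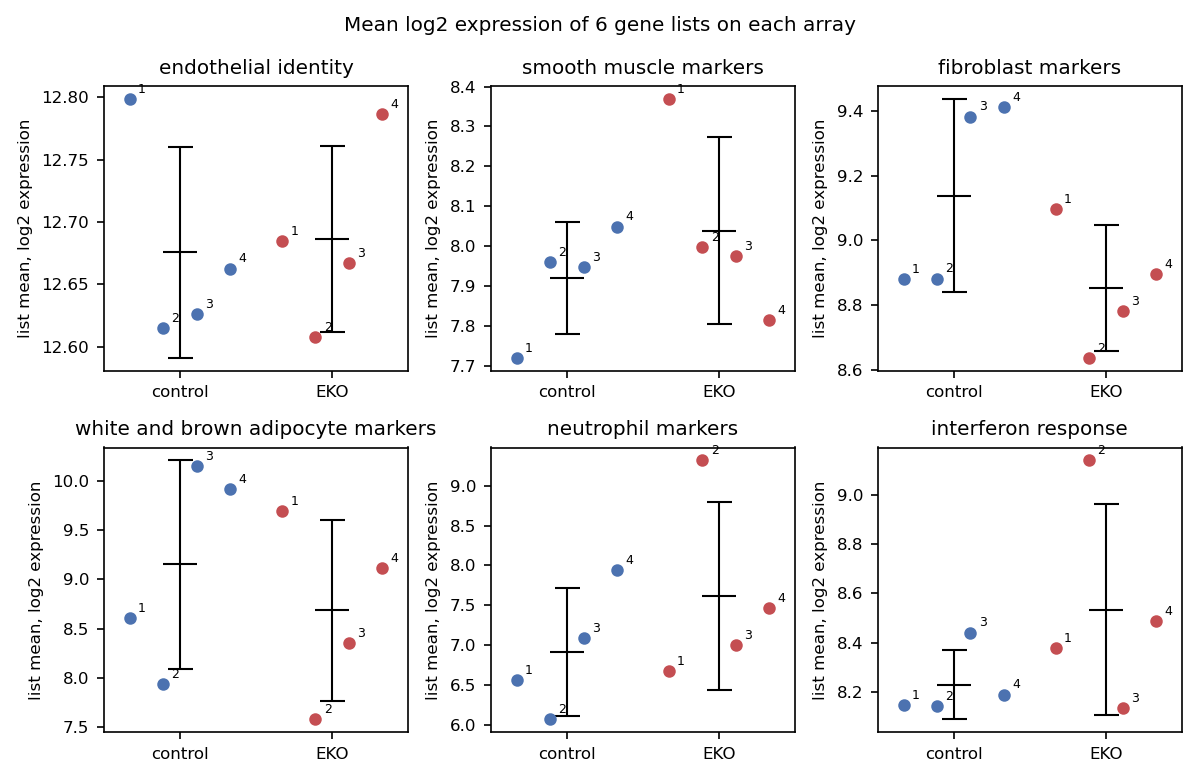
Mean log2 expression of 6 gene lists on each array, numbered by replicate; bars are the mean ± SD of 4 arrays. Adipocyte markers spread widely within both groups (SD 1.05 and 0.92), and EKO array 2 is highest for the neutrophil and interferon lists.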

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

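Of the tests on single patterns in this part, those of signal contrast, of a single array, of the split of predicted symbols and of shared kallikrein probes were chosen after the result they measure, or values close to it, had been seen. Among 340 groups of 4 arrays, 25 held an array far from the other 3, where chance gives about 17. EKO array 2 held 7 of the 25, control array 4 and EKO array 1 held 5 each, control arrays 1 and 2 held 3 each, and control array 3 and EKO array 4 held 1 each.

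On EKO array 2, the array stood high for the leukocyte adhesion list (10.6), the lymphocyte list (7.10), Ngp (8.60) and Cd3e (7.61), and low for the reported MEF2 targets (9.75), Acvrl1 (12.5) and Sesn2 (6.44). On control array 4, the muscle gene Tnnt3 read 9.29, Ckm 7.15, the striated muscle list 7.75, Pdpn 7.51 and Cd3g 7.04, all high. EKO array 1 was high for Lox (10.8), Flt4 (8.92) and the striated muscle list (7.33), and low for Inha (6.75) and Myocd (6.12). Control array 1 was high for Vegfd (9.59) and Ghrl (6.16) and low for Trp53inp1 (8.75). Control array 2 was high for Trav13n-2 (7.12) and low for Mmrn1 (5.57) and the macrophage list (6.85). Control array 3 was high for the interferon list (8.44), and EKO array 4 was low for Myc (6.94).

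Across the 35 splits of the 8 arrays into 4 and 4, all 35 gave at least as many genes past the threshold as the real split. The real count was 0, which no split can go under, so this comparison decides nothing about chance. The highest other split gave 446 genes. It set control arrays 1 and 2 and EKO arrays 2 and 3, the 4 with the lowest adipocyte marker means, against the rest, which points to a structure of the samples. At an unadjusted p under 0.05, 4 of the 35 splits gave as many genes as the real 1449, the highest other giving 2408. For lists past the threshold 33 of the 35 gave as many as the real 1, the highest other giving 12. Chance cannot be excluded for either count.

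The first pattern weighed is the higher interferon list. In 8 of the 35 splits camera gave this list a p as small as the real one, 0.000127, and the smallest of the others was 2.26e-07, so chance cannot be excluded. Without EKO array 2, left out as the highest EKO array for this list, the mean difference fell to a share of 0.337 of its full value. Some fall was built in by that choice. A large part of the difference thus came from that single array, in the mean of this list. Its difference stood at the 100th percentile of random lists matched on level, which a trend with level alone would not give, yet with the signal contrast as a covariate it went from 0.30 to 0.19 (adjusted p 0.296), and EKO array 2 also had the lowest contrast (3.19), so the contrast and that animal cannot be told apart. Deletion of Mef2c and exposure to tamoxifen stay open, as untested.

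The second is that predicted and clone symbols, 4831 of the 16232 genes tested, were more often higher. At an unadjusted p under 0.05 by limma, 634 of them were higher and 87 lower, against 246 and 482 of the other symbols. The per-array gap between the medians of the classes differed by 0.17 between the groups, with an exact permutation p of 0.0857, so chance cannot be excluded. With group means taken off, the gap and the signal contrast correlated at r = -0.558 (permutation p = 0.149, adjusted over 3 relations 0.149; r = -0.554 without the 2 farthest arrays) and Spearman rho = -0.762 (permutation p = 0.0372, adjusted 0.0558). Without that step r was -0.696 (permutation p = 0.0516, adjusted 0.0774; Spearman rho = -0.643, permutation p and adjusted p = 0.0969) but -0.272 without the 2 farthest arrays, so the pooled relation rests on those. With so few arrays a part played by the contrast cannot be told apart from a difference between the groups.

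The third is the lower Klk1b22. Salivary gland tissue on some arrays is argued against: 9 gland markers with a probe set, outside the kallikreins, had a median difference of 0.0379, and 8 of them read 5.95 at the highest on a control array, below the level filter of 6.14, while Klk1b22 averaged 11.96 there; Amy1, the other, went from 8.78 to 8.44 (-0.34). Shared probes may contribute, since deviations from the group means correlated between Klk1b22 and 10 other family members with a median r of 0.849 over the 8 arrays, although true joint expression would give the same. Klk1 (0.47) and Klk1b5 (0.33), chosen after their values were seen, were not lower. Deletion of Mef2c and tamoxifen stay open, as untested.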

How the results depend on the processing

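The covariates for adipocyte markers and signal contrast, the restriction to protein-coding genes, and the set tests with an estimated correlation or fry within other settings were chosen after seeing the data; the other alternatives were planned. No gene passed the adjusted threshold with limma under any setting run, nor with Welch's test (1219 genes at an unadjusted p under 0.05, against limma's 1449). At an unadjusted p under 0.05 and at least 1.5-fold, 82 genes were counted, 50 higher and 32 lower. Mef2c lay between -0.12 and 0.07, never past the threshold, and between -0.12 and 0.04 when single arrays were left out. The 20 genes named by p kept their direction in all 440 values from other settings, and 0 passed. Their groups did not overlap, so leaving out a single array could not turn a sign. Several other settings, such as Welch's test, leave the difference unchanged. The kept direction is therefore largely built in and is no evidence of stability. The signal contrast between control probe sets marked pos and neg was lowest on EKO array 2 (3.19). Whether it limits the differences was not tested.

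The number of lists past the threshold, 1, became 2 without a level filter, 0 with the filter at the 75th percentile, 3 with quantile normalization, 3 with the smooth muscle covariate, 2 with the array median covariate, 0 with an estimated correlation, 0 with fry, 0 with the signal contrast covariate, 4 with protein-coding genes, and 0 to 3 when single arrays were left out. It was 0 without EKO array 2, 2 without control array 3 or without EKO array 3 or 4, and 3 without control array 2 or without EKO array 1. The added lists were the fibroblast, leukocyte adhesion, elastic fibre, adipocyte, fatty acid, neutrophil and immediate early ones. In the settings where camera called a list, none of the calls held with an estimated correlation (adjusted p 0.742 to 0.999) or with fry (0.187 to 0.994; not run with array weights). The interferon list stayed higher in all settings, but missed the threshold at 0.33 with the 75th percentile filter (adjusted p 0.286), 0.13 with the array median covariate (0.408), 0.30 with an estimated correlation (0.981) and with fry (0.895), and 0.19 with the signal contrast covariate (0.296). Leaving out single arrays gave 0.10 to 0.44, missing the threshold without EKO array 2 (0.0819). Over its settings, changed singly, the adjusted p ran from 7.96e-06 to 0.981. The cause was not tested, beyond fewer genes entering at the stricter filter.

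A sign was counted as reversed where it turned and either setting made a call or the value moved by over 1 SE. With the array median as a covariate, the values were 0.69 for adipocyte markers and 0.51 for fatty acid handling (both then past the threshold, with adjusted p 0.927 by an estimated correlation and 0.826 by fry), 0.50 for striated muscle, 0.23 for macrophages, 0.14 for p53 and senescence, 0.074 for cholesterol synthesis, 0.070 for MEF2 targets, 0.029 for elastic fibre and 0.0031 for fibroblasts. For genes they were Tnnt3 0.89, Pparg 0.76, Myl1 0.59, Acadm 0.56, Cox8b 0.52, Fabp4 0.50, Adipoq 0.32, Retn 0.21, Clock 0.20, Upk3b 0.17, Itgam 0.15, Fbln1 0.12, Gsta4 0.11, Pdpn 0.091, Dcn 0.088, Loxl1 0.056, Skil 0.0072, Ltf -0.022 and Dbp -0.084. With the signal contrast covariate they were 0.32 for adipocyte markers, 0.23 for fatty acid handling, 0.10 for p53 and senescence and 0.015 for cholesterol synthesis, and Pparg 0.33, Fabp4 0.33, Cox8b 0.30, Acadm 0.22, Gsta4 0.034 and Clock 0.017. Leaving out single arrays gave Cd3e -0.084 to 0.37 and Ngp -0.060 to 0.95 (lowest without EKO array 2), Pdgfc -0.26 to 0.022 (highest without control array 2) and Tnnt3 -0.65 to 0.57 (highest without control array 4). The cause was not tested. As given above, the array median was highest where adipocyte markers were lowest, so reversals with that covariate may follow from the covariate itself. In all, 75 of 3136 values of named genes and 78 of 682 values of lists had the other sign, and 14 of the 34 planned lists reported turned sign when some single array was left out. The totals of values include settings that cannot move the difference, such as Welch's test for genes and fry for lists. Among settings that can move it, the shares with the other sign are therefore higher.

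No label says that the replicate numbers pair the samples. Deviations of same-numbered arrays from their group means correlated at -0.16, 0.21, -0.24 and 0.13. Of 8 arrays, 0 correlated best with their own number. These correlations take in all variation between arrays, that of adipocyte markers included, so they cannot exclude a pairing. With the replicate number as a block, limma called 0 genes and camera 2 lists.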

Other observations

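A list of erythroid and haem synthesis genes, made after seeing the data, was lower in EKO aortas in 13 of 13 tested members. The list averaged 10.1 ± 0.39 in control and 9.62 ± 0.09 in EKO arrays (SD, n = 4), a difference of -0.53 with an exact permutation p of 0.0857. Fech, an enzyme of haem synthesis, differed by -1.08, Alas2 by -1.02, and the globin genes Hbq1a and Hbq1b by -0.94 and -0.88. Adjusted over the list alone 6 members passed by limma, but the list was chosen from these values, so this is not independent evidence. Control array 2 read 9.63, within the EKO range of 9.51 to 9.70, and without it the difference was -0.70.

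A list of immunity-related GTPases, which interferon-gamma induces, was likewise made after seeing the data, and 10 of 10 members were higher in EKO aortas. Iigp1 differed by 1.61, Gbp2 by 0.84 and Irgm2 by 0.76, and 0 members passed adjusted over the list alone by limma, or over all genes. Gbp2 is a guanylate-binding protein and also belongs to the planned interferon list, so the lists overlap. The list averaged 10.3 ± 0.14 in control and 11.1 ± 1.14 in EKO arrays (exact permutation p = 0.114). EKO array 2 read 12.8, and without it the difference was 0.32 in place of 0.87.

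The kallikrein 1 family, listed after seeing the data, had 11 tested members, 9 of them lower in EKO aortas, with a mean difference of -0.82 (exact permutation p = 0.200). Klk1b22 and Klk1b8 (-1.01) passed adjusted over the list alone by limma, but the list was made because of the Klk1b22 value, so this is not independent evidence. Without control array 1 the mean was -0.50, and without EKO array 4 it was -1.22. Of the salivary gland list 1 gene was tested, Amy1, at -0.34 (exact permutation p = 0.257). It was at -0.13 without control array 4 and at -0.53 without control array 2.

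Among 192 tested pseudogenes of ribosomal proteins, a class looked at after the named genes were seen, 177 were higher and 15 lower in EKO aortas, with a median difference of 0.13. These genes are not independent of each other, and 6 of them are among the 10 genes named as highest, so the class is not independent evidence. The class mean was 13.28 ± 0.04 in control and 13.43 ± 0.06 in EKO arrays (SD, n = 4), a difference of 0.15 with an exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give, and 0.13 to 0.18 with single arrays left out. Predicted and clone symbols as a whole differed in their array median by 0.10 (exact permutation p = 0.0857), other symbols by -0.07 (0.171) and the signal contrast by -0.12 (0.229).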
